A study of Mus musculus with 16 samples.

How the data were processed

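Messenger RNA and long noncoding RNA were measured in 16 hearts of C57BL/6 mice, each extracted with TRIzol and read on its own 1-colour Agilent array. Groups were taken from the labels: control, T1R1, T2R1 and T3R1, with 4 hearts each. Per the file headers, the processed intensity values of each array were made with Feature Extraction 10.7.3.1, which subtracted the background and removed the spatial trend within the array and did not normalize between arrays. Per the file headers, the mean spot intensity and the median local background were left uncorrected, and the other columns hold flags of 0 or 1 set by the scanner software. The value table that the authors deposited holds log2 values that had been quantile-normalized between arrays; their ranks equal those of the mean spot intensity, so no background had been subtracted, and their median is 6.10. The authors' method for that table is not given in the sources used here.

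The main analysis started from the processed intensity. Spots marked as outliers by the scanner software were left out, the 75th percentile of the log2 values of each array was subtracted, and the spots of a probe were averaged. A probe was kept where it was well above background on all 4 arrays of at least 1 group, which left 31390 of 55681 probes. Each gene name was then represented by its probe of highest mean, giving 22648 tested features: 17501 gene names, 3045 long noncoding RNA probes and 2102 unnamed transcripts. Among these, 102 values were missing. Probe names were brought up to date through a RefSeq accession for 26756 probes and as current symbols for 3824, and 25101 kept the name in the file. Positions are those of the array design.

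A linear model over the 4 groups was fitted with limma 3.58.1 in R 4.3.3 and its variances were moderated by empirical Bayes, with 12 residual and 2.26 prior degrees of freedom. Contrasts compared each exposure with control, the exposures with each other and the mean of the 3 exposures with control, and a moderated F test covered all 4 groups. P values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Replicate numbers follow the order of the animal numbers in the sample titles, which state no pairing. Only 5 of 16 arrays correlated best with an array of their own replicate number, and the fit was unpaired. Where a probe was well above background on no array of 1 group, the fold change is given as at least a bound, for which each dim value was raised to the lowest well-above-background signal of its array.

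Gene lists for heart, stress, immune and cell type programs, 44 in all, were written before the data were examined, as were the comparisons, the thresholds, most alternatives and the rule by which genes are named. Of 932 list entries 925 were on the array, and 1 list had fewer than 5 measured genes and was not tested. Lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated for each list and with fry. Counts within a list are given with p values adjusted over all genes, and with p values adjusted over the list alone. Genes are named if they were among the 10 highest or lowest fold changes past the threshold with arrays of the groups not overlapping, among the 4 smallest p values of a described list, or among 16 genes fixed beforehand; some members of lists are not reported here. Correlations between the fold changes of exposures were compared with 1000 simulated pairs and with controls split between the exposures.

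The pipeline was tested on simulated data for T3R1 against control. Each gene had its residual spread over all 4 groups, the same on every array, so an array apart from its group was not simulated. With 200 genes changed in each of 20 draws it recovered 27.2% of changes of 0.5 on the log2 scale, 68.1% of changes of 1 and 92.7% of changes of 2, and 5.20% of calls were false. With no change added it made 0 calls by limma. The simulated genes were independent of each other, so this gave no test of the false calls of camera: with real arrays grouped at random the median number of lists camera called in T3R1 against control was 19. A simulated gene list shifted by 0.5 was called in 20 of 20 draws. Genes that changed had 842 other probes in T1R1 against control, of which 178 passed in the same direction and 13 in the opposite one. In T2R1 these were 529 and 29 of 1601, and in T3R1 15 and 0 of 65, and the remaining probes did not pass.

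Alternatives covered the background correction (normexp, offset 50), the scaling (quantile, or the median of each array), the authors' values, the filter on dim probes, every probe on its own, the samples in the fit, an intensity trend with a robust prior, array weights, the replicate block, the thresholds, and leaving out each array in turn. The lists of T2R1 against T1R1, the fold changes without control replicate 1 and the fits without both that array and T1R1 replicate 1 were added after the files had been seen. Slide and scan could not be fitted as blocks, because each slide held 2 whole groups. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R used data.table in version 1.17.8. Spike-in and other control spots did not enter the fits and served only for quality values of the arrays. No array was left out of the main analysis.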

Results

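Gene expression was measured in whole hearts of C57BL/6 mice after repeated encounters with an aggressor mouse, a model of posttraumatic stress disorder. The 16 arrays, 1 heart each, formed 4 groups of 4. In T1R1, T2R1 and T3R1 the mice were exposed for 1, 2 or 3 days and then rested for 1 day. Control mice sat in the same mesh boxes in a cage without an aggressor, and the labels place them in the arm of 2 days with 1 day of rest. T1R1 and T3R1 therefore had no control labelled for their own duration. The general treatment text of the labels gives longer exposures than the group names do, and the group names were followed. RNA labelled with the dye Cy3 was read on a 1-colour oligonucleotide array. Each array held 59305 spots that were not controls, and from 46.5% to 67.1% of these were well above background. The brightness at the 75th percentile was 547 scanner units in control replicate 1, between 257 and 273 in control replicates 2 to 4, and between 283 and 407 on the 12 exposed arrays. The number of arrays per group limits the precision of every value below.

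The 16 arrays lay on 2 slides. Control and T3R1 shared a slide and a scan, and T1R1 and T2R1 shared the other slide and scan. For T1R1 or T2R1 against control or T3R1, slide and exposure therefore cannot be told apart, whereas T3R1 against control and T2R1 against T1R1 were compared within a slide. Control replicate 1 lay away from control replicates 2 to 4: its mean correlation across genes was 0.988 with the T3R1 arrays and 0.970 with the other controls. Genes are not independent replicates, so these correlations carry no test. Counts of genes without that array are given beside those with it for every comparison that is not 0, and fold changes without it for some genes.

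**Figure D1:**
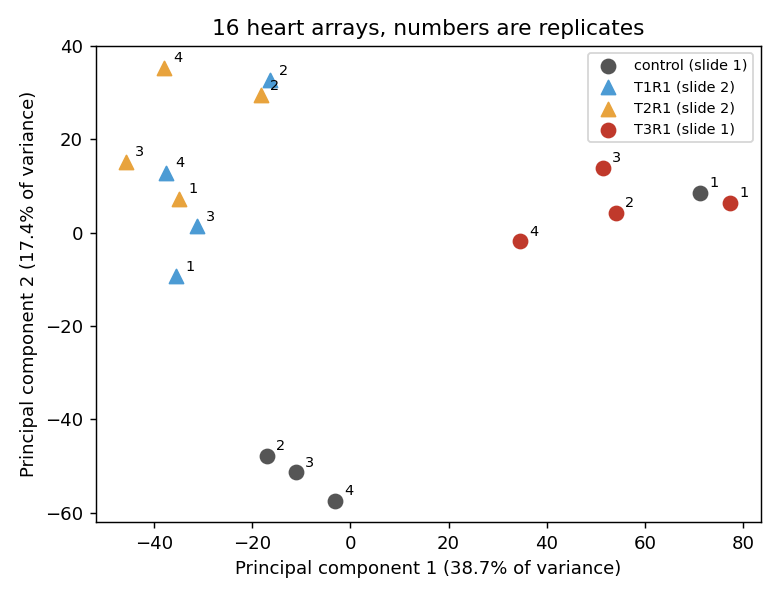
The first principal component of the log2 values of the tested genes (x axis, 38.7% of the variance) against the second (y axis, 17.4%), for the 16 arrays coloured by group, with circles on slide 1, triangles on slide 2 and numbers for replicates. Control replicate 1 lies among the T3R1 arrays, away from control replicates 2 to 4.

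T1R1 was compared with control to ask what 1 day of exposure leaves in the heart a day later. Clock genes moved in opposite directions: the outputs Gm129 and Dbp and the repressor Nr1d1 were higher, and the activator Arntl was lower. T1R1 and control lay on different slides, so slide and exposure cannot be told apart for these genes. Time of collection was not part of the fit. The hormone-binding protein Crhbp and the coagulation genes F7, Klkb1 and Fga were higher. The nerve and fat marker lists were called downward at a preset correlation, but not with an estimated correlation. The matrix and cell cycle lists were not called. Of 22648 genes tested, 2231 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1755 higher and 476 lower. At an unadjusted p under 0.05 there were 5862, where 1132 were due by chance. The changed features comprised 1282 genes with a gene name, 698 long noncoding RNA probes and 251 unnamed transcripts.

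In the clock list of 18 measured genes, 4 were higher and 1 was lower in T1R1, and adjusted over the list alone 4 were higher and 3 lower. Gm129, the circadian repressor Ciart, was 4.64-fold higher (log2 fold change 2.22 ± 0.39, SE, n = 4 per group, adjusted p = 0.00354). Its probe lies on chromosome 3 at 95682433 to 95682492 of the mm9 build, to which all positions here refer. Dbp, a clock-output transcription factor on chromosome 7 at 52965461 to 52965520, was higher by 0.85 ± 0.16 (adjusted p = 0.00545). Nr1d1, the repressor of Arntl, rose by 1.27 ± 0.30 (adjusted p = 0.0166). Arntl, the core clock activator on chromosome 7 at 120457261 to 120457320, fell by 1.17 ± 0.27 (adjusted p = 0.0139). The list as a whole was not called: its median was 0.05 (camera adjusted p = 0.63, adjusted p = 0.954 with an estimated correlation). The glucocorticoid list held 27 measured genes. Of these 1 was higher, over all genes and adjusted over the list alone: Tat, a hormone-induced amino acid enzyme, by 0.99 ± 0.24 (adjusted p = 0.0173). Its median was -0.18 and its mean 0.06, and the test pointed down without passing (adjusted p = 0.773, and 0.972 with an estimated correlation). Fkbp5, a chaperone induced by glucocorticoids, was at -0.31 ± 0.15 (adjusted p = 0.217), and Per1 at 0.47 ± 0.22 (adjusted p = 0.19).

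Crhbp, which binds corticotropin-releasing hormone, was 3.61-fold higher in T1R1 (1.85 ± 0.31, adjusted p = 0.0029, chromosome 13 at 96201903 to 96201962). Cd247, the zeta chain of the T cell receptor, rose by 0.91 ± 0.16. Thymus markers, too few for a test, had a median of 0.87. Against control replicates 2 to 4 they lay at 2.51 on T1R1 replicate 1 and between -0.05 and 0.42 on the other T1R1 arrays. Cd247 stayed past the threshold without each array in turn, so thymus RNA on T1R1 replicate 1 alone was not the whole source. Thymus RNA on the other arrays was not excluded. In the coagulation list of 26 measured genes, 3 were higher, and 3 adjusted over the list alone: F7 by 0.69 ± 0.13, Klkb1 (prekallikrein) by 1.16 ± 0.26 and Fga (fibrinogen alpha) by 0.85 ± 0.22. The list was not called (median 0.14, adjusted p = 0.245, and 0.954 with an estimated correlation). These 3 genes and Tat are expressed mainly in liver. The 7 liver markers measured had a median of 1.39, or 2.10 without control replicate 1, and 4.10 on T1R1 replicate 4 against control replicates 2 to 4. The liver list was not called (adjusted p = 0.469, and 0.954 with an estimated correlation), and liver RNA was not excluded as the source. Other genes higher in T1R1 were the transcription factor Bhlha9 (1.86 ± 0.39), the predicted gene Gm8777 and the receptor gene Gpr115. Gm8777 and Gpr115 were each well above background on 1 of 4 control arrays, so their sizes are not given. Scube3, a secreted ligand of the TGF-beta receptor, was at least 1.99-fold lower (adjusted p = 0.00174, chromosome 17 at 28311682 to 28311741), and Gnal, a G protein subunit, at least 1.22-fold. With no filter on dim probes another probe represented Gnal, and its direction turned. Lower by 1.17 to 1.38 on the log2 scale were N4bp2l1, Stac, Itga8 (integrin alpha 8), Omd (osteomodulin) and Frat1. On every gene named for its size here and below, the arrays of the groups compared did not overlap. The naming rule required this, so it is no separate support, and 2.86% of unchanged genes would show it by chance.

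Genes of muscle stress and repair did not pass, and several depended on control replicate 1. Nppb was at 0.88 ± 0.49, Myh7 at 0.93 ± 0.60, Nppa at -0.08 ± 0.16, Col1a1 at -0.27 ± 0.42, Col3a1 at -0.10 ± 0.50, Postn at -0.16 ± 0.64 and Mki67 at -0.99 ± 0.71, with adjusted p from 0.277 to 0.929. Without control replicate 1 the values of Col1a1, Col3a1 and Postn turned to 0.32, 0.61 and 0.75, Myh7 was at 1.48 and Mki67 at -0.04, and none passed. Lcn2, a neutrophil and acute-phase lipocalin, was at 1.99 ± 0.71 (adjusted p = 0.0914), and without control replicate 1 it was at 2.80 and passed. S100a8 (1.10 ± 0.82), Hspa1a (1.24 ± 0.71), Pdk4 (-0.37 ± 0.41), Ucp3 (0.17 ± 0.09) and Hba-a1 (-0.20 ± 0.31) also stayed short of the threshold.

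Of the 43 lists tested, camera called 4 in T1R1, all lower. None was called with an estimated correlation (adjusted p = 0.954 for each), and fry called 0 in a common direction and 6 in either direction. An unadjusted camera p under 0.05 was found for 13 lists. The adipocyte markers had a median of -2.43 over 14 genes, of which 3 were lower, or 12 adjusted over the list alone (adjusted p = 3.84e-05); the lead members were Ucp1 of brown fat (-5.88 ± 1.68), Adipoq (-2.89 ± 0.87) and Cidea (-0.82 ± 0.24). Single arrays stood apart: against control replicates 2 to 4 these markers lay at 0.47 on T1R1 replicate 1 and from -3.34 to -2.42 on the other T1R1 arrays, and at 1.67 and 1.45 on control replicates 1 and 4 against -0.77 and -0.68 on the other 2. Nerve and Schwann cell markers had a median of -0.30 over 13 genes, of which 4 were lower, or 6 adjusted over the list alone (adjusted p = 0.0102). Nefl (neurofilament light) was at -2.31 ± 0.48, Prph (peripherin) at -2.36 ± 0.53 and S100b at -1.09 ± 0.27. Cholesterol synthesis had a median of -0.32 over 20 genes, of which 2 were lower, Hmgcs1 (-0.41 ± 0.10) and Fdps (-0.53 ± 0.14); adjusted over the list alone 1 was higher and 7 were lower (adjusted p = 0.00623). Ribosomal proteins had a median of -0.11 over 40 genes with 0 past the threshold, over all genes and adjusted over the list alone (limma, adjusted p of the list by camera = 0.000566). This median was -0.03 with quantile normalization and -0.01 on the authors' values, and without control replicate 1 these turned to 0.05 and 0.10. Without control replicate 1 or without T1R1 replicate 3 the cholesterol list was no longer called, with medians of -0.14 and -0.24. The number of lists called was 23 without control replicate 1, 8 without control replicate 2 and 11 without T1R1 replicate 1.

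Without control replicate 1, 4046 genes changed in T1R1, 1857 higher and 2189 lower, and 1943 of the 2231 were among them in the same direction. The count was 1454 without control replicate 4 and 1339 without T1R1 replicate 4. Of the 38 genes picked by the naming rule and past the threshold, 19 stayed past it without each array in turn: 17 fell short without control replicate 4, 14 without T1R1 replicate 3, 14 without T1R1 replicate 4, 11 without T1R1 replicate 2 and 10 without control replicate 3. Leaving out control replicate 1, the log2 fold change was 2.30 for Gm129, 1.70 for Crhbp, -1.24 for Arntl and -2.07 for Scube3. T1R1 replicate 1 lay nearer to control replicates 2 to 4 than the other T1R1 arrays did. Its label was not settled: its correlations lay from 0.984 to 0.989 with the T2R1 arrays, on the same slide, and from 0.986 to 0.988 with control replicates 2 to 4. With the other T1R1 arrays they lay from 0.981 to 0.984, about as those arrays did with each other. The share of changed genes that were higher, 78.7%, depended on the processing: it was 51.7% with quantile normalization, 50.8% after normexp background correction, 46.0% on the authors' values and 5.81% with each array scaled to its median. With that last scaling the median of all genes against control went from -0.01 to -0.44 in T1R1 and from 0.02 to -0.37 in T2R1, and the medians of lists shifted by as much.

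**Figure D2:**
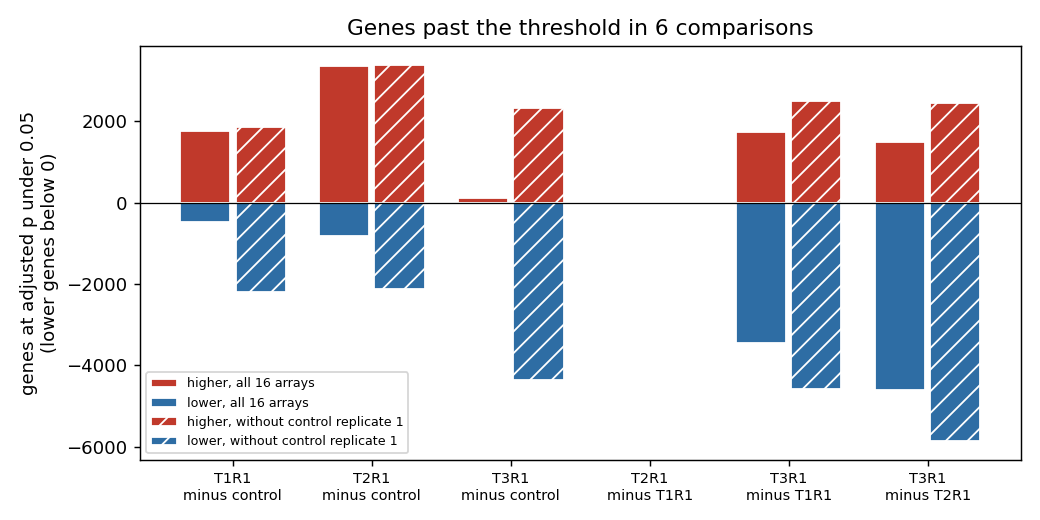
Number of genes at an adjusted p under 0.05 (y axis) in each of 6 comparisons (x axis), with bars for genes higher and genes lower and hatched bars for the same counts without control replicate 1. For T3R1 minus control the total is 157 with that array and 6672 without it.

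T2R1 was compared with control to ask what 2 days of exposure leave. The clock genes Gm129, Dbp and Arntl again differed from control, now with Per1 and Cry1, and again between slides. The neutrophil list was called upward at a preset correlation, but not with an estimated correlation or without control replicate 2. Lcn2 and the fetal myosin Myh7 were higher. The xenobiotic enzyme Cyp1a1, the nerve genes Nefl and Prph, the GTPases Gbp3 and Gbp4 and the atrial genes Dkk3 and Sln were lower. The nerve, interferon and atrial lists were called downward at a preset correlation, but not with an estimated correlation. In all 4167 genes changed, 3354 higher and 813 lower, and 6988 had an unadjusted p under 0.05. The balance moved with the processing here too. Most stayed higher with quantile normalization, at 1850 higher and 1191 lower, on the authors' values, at 2153 and 1640, and after normexp correction, at 1762 and 833. With each array scaled to its median most were lower, at 1382 and 7720.

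Neutrophil markers had a median of 1.10 over 12 genes in T2R1, and 7 were higher, or 8 adjusted over the list alone. The median was 0.63 after normexp correction, 0.67 on the authors' values and 1.71 without control replicate 1. Camera called the list (adjusted p = 0.0122, and 0.995 with an estimated correlation), and it was the only list that fry called in a common direction (adjusted p = 0.0276), where 8 lists were called in either direction; without control replicate 2 camera no longer called it, at a median of 0.85. Retnlg, a resistin-like protein of neutrophils on chromosome 16 at 48874468 to 48874527, was 7.52-fold higher (2.91 ± 0.81, adjusted p = 0.0228). The protease inhibitor Stfa2l1 was higher (adjusted p = 0.00998), with 1 of 4 control arrays well above background, so its size is not given. The calprotectin subunit S100a9 rose by 2.46 ± 0.81 (adjusted p = 0.048), whereas its partner S100a8 was at 2.44 ± 0.82 (adjusted p = 0.0517). Also higher were Stfa2 by 1.00 ± 0.24, Elane (neutrophil elastase) by 0.59 ± 0.16 and Ly6g by 0.46 ± 0.11. Lcn2 was 5.95-fold higher (2.57 ± 0.71, adjusted p = 0.0208), with overlapping arrays, and higher by 3.38 without control replicate 1. The T cell genes Cd247 (1.10 ± 0.16), Prf1 (0.73 ± 0.17) and Cd3e (0.63 ± 0.19) rose, 3 of 14 T and NK cell markers measured, and 3 adjusted over the list alone; the list was not called (median 0.20, adjusted p = 0.5, and 0.995 with an estimated correlation). Thymus markers, too few for a test, had a median of 0.81 in T2R1 and lay from 0.52 to 0.91 on its arrays against control replicates 2 to 4, so thymus RNA was not excluded as the source. F7 rose by 0.68 ± 0.13, Klkb1 by 1.03 ± 0.26 and Fga by 0.86 ± 0.22, where liver markers had a median of 0.61, or 1.27 without control replicate 1.

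Gm129 was 6.55-fold higher in T2R1 (2.71 ± 0.39, adjusted p = 0.00055), Dbp 2.23-fold (1.16 ± 0.16, adjusted p = 0.000507) and Per1 1.70-fold (0.76 ± 0.22, adjusted p = 0.0249). Arntl fell by 1.65 ± 0.27 (adjusted p = 0.00104) and the repressor Cry1 by 0.69 ± 0.15 (adjusted p = 0.00673). In the clock list 5 genes were higher and 3 lower, or 6 and 3 adjusted over the list alone, at a median of 0.06 (camera adjusted p = 0.774, and 0.995 with an estimated correlation). In the glucocorticoid list 5 were higher and 1 lower, over all genes and adjusted over the list alone, among them Tat (1.14 ± 0.24) and the metallothionein Mt1 (0.77 ± 0.19). Its median was 0.09 (adjusted p = 0.848, and 0.995 with an estimated correlation). Bhlha9 was higher by 2.46 ± 0.39. The odorant receptor gene Olfr822 was at least 2.87-fold higher and the predicted gene Gm11567 at least 2.78-fold. Myh7, the fetal beta myosin on chromosome 14 at 55589581 to 55589640, was 3.82-fold higher (1.93 ± 0.60, adjusted p = 0.0385, and 2.48 without control replicate 1), and the myosin-binding protein Mybpc2 rose by 1.29 ± 0.25.

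Cyp1a1, a detoxifying oxygenase on chromosome 9 at 57551535 to 57551594, was at least 6.92-fold lower in T2R1 (adjusted p = 0.00638). Nefl was at least 3.40-fold lower and Prph fell by 2.03 ± 0.53; with S100b, 3 of 13 nerve and Schwann cell markers were lower, and adjusted over the list alone 3 were lower and 1 higher (median -0.41, adjusted p = 0.0154, and 0.995 with an estimated correlation). The neuronal vesicle gene Nsg2 fell by 2.29 ± 0.74, Acsm3 by 2.13 ± 0.61 and the chloride channel gene Clic6 by 1.76 ± 0.56. Zcchc12, Gnal and Ucma were at least 1.55, 1.46 and 1.56-fold lower, though the direction of Gnal turned here too with no filter on dim probes. Of 34 interferon-induced genes 4 were lower, and 4 adjusted over the list alone (median -0.26, adjusted p = 0.000102, and 0.995 with an estimated correlation): Gbp3 (-0.75 ± 0.16), Iigp1 (-0.67 ± 0.15), Gbp4 (-0.73 ± 0.17) and Ifit3 (-0.64 ± 0.19). Atrial markers had a median of -0.64 over 10 genes, with Dkk3 (-1.11 ± 0.26) and Sln (sarcolipin, -0.86 ± 0.28) lower, 2 also adjusted over the list alone (adjusted p = 0.00634, and 0.995 with an estimated correlation).

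The other 4 lists called in T2R1 were lower too, each with an adjusted p of 0.995 with an estimated correlation: endothelial markers (median -0.16 over 14 genes; Cldn5 -0.69 ± 0.19 and Egfl7 -0.37 ± 0.12), angiogenesis (-0.11 over 26; Aplnr -0.70 ± 0.21), cholesterol synthesis (-0.21 over 20; Insig1 -1.09 ± 0.29) and adipocyte markers (-1.504 over 14). Nppb (1.15 ± 0.49), Nppa (0.11 ± 0.16), Hspa1a (1.19 ± 0.71), Hba-a1 (0.26 ± 0.31), Fkbp5 (-0.12 ± 0.15), Pdk4 (-0.30 ± 0.41) and Ucp3 (-0.06 ± 0.09) did not pass. Genes past the threshold numbered 2 of the endothelial list, 1 of angiogenesis, 3 of cholesterol synthesis and 0 of the adipocyte list; adjusted over the list alone they numbered 2, 0, 3 and 0. Single arrays ended calls: without control replicate 1 the cholesterol (-0.12), interferon (-0.16) and adipocyte (-1.07) lists, without control replicate 2 the angiogenesis list (-0.10), without control replicate 3 the angiogenesis (-0.06) and endothelial (-0.09) lists, without T2R1 replicate 1 the cholesterol (-0.22) and angiogenesis (-0.11) lists and without T2R1 replicate 4 the adipocyte list (-0.88). Leaving out control replicate 1, 16 lists were called and 5514 genes changed, 3538 of them shared in the same direction. With control replicates 2 to 4 alone, 23 of 40 collagen and fibrosis genes and 24 of 31 cell cycle genes were higher, against 2 and 0 with that array. Col1a1 was at 0.80 ± 0.42 with all controls and 1.40 without control replicate 1, Col3a1 at 1.16 ± 0.50 and 1.86, Postn at 1.05 ± 0.64 and 1.96, and Mki67 at 0.65 ± 0.71 and 1.61. Of 54 genes named by rule and past the threshold, 29 stayed past it without each array in turn: 16 fell short without T2R1 replicate 3, 16 without T2R1 replicate 4, 14 without T2R1 replicate 2, 13 without each of T2R1 replicate 1, control replicate 3 and control replicate 4, 11 without control replicate 2 and 10 without control replicate 1.

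T3R1 was compared with control to ask what 3 days of exposure leave, within a single slide. Matrix genes were higher: fibrillar collagens, the enzymes that cross-link them and the fibroblast proteins Cthrc1, Postn and Lrrc15. Control replicate 1 shared this pattern. Relative to control replicates 2 to 4, its collagen list lay at 1.497, where the T3R1 arrays lay from 1.42 to 1.98. At a preset correlation the cell cycle and macrophage lists were called upward and fatty acid oxidation, oxidative phosphorylation and ion channels downward, but no list was called with an estimated correlation. Of these lists only the cell cycle had a gene past the threshold, and it had 1. The interferon-induced GTPases Gbp4 and Gbp5 were lower. With all 4 controls 157 genes changed, 114 higher and 43 lower, and 5085 had an unadjusted p under 0.05. Without control replicate 1 the count was 6672, 2316 higher and 4356 lower, which held all 157 in the same direction.

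Cthrc1, a secreted collagen-modulating protein on chromosome 15 at 38918358 to 38918417, was higher in T3R1 (adjusted p = 0.0472). Crct1, a gene of the epidermal differentiation cluster on chromosome 3 at 92818192 to 92818251, was higher too (adjusted p = 0.0315). Of the 4 control arrays only 1 was well above background for either gene, so the size of these changes is not given. The cross-linking enzymes Lox and Loxl2 rose by 3.93 ± 0.83 and 2.52 ± 0.52, or by 4.99 and 3.18 without control replicate 1. Col3a1 (chromosome 1 at 45405589 to 45405648) was 5.75-fold higher (2.52 ± 0.50, adjusted p = 0.0379) and Col1a1 (chromosome 11 at 94813115 to 94813174) 4.93-fold (2.30 ± 0.42, adjusted p = 0.0275). Periostin, Postn, was 8.46-fold higher with overlapping arrays (3.08 ± 0.64, adjusted p = 0.0443). The fibroblast membrane protein Lrrc15 was higher, with 1 of 4 control arrays well above background, so its size is not given either. The matrix protein Cilp rose by 2.50 ± 0.52, fibrillin Fbn1 by 2.04 ± 0.44 and the mitotic enzyme Ube2c by 2.13 ± 0.44. Against control replicates 2 to 4 the log2 fold change was 3.23 for Col3a1 and 3.99 for Postn. Gbp4 (chromosome 5 at 105544852 to 105544911) fell by 1.41 ± 0.17 (adjusted p = 0.00626), and Gbp5 by 0.87 ± 0.17. The protease inhibitor gene Cst9 fell by 1.34 ± 0.26, Cib3, a calcium-binding protein, by 1.26 ± 0.23, and 1810011O10Rik, now called Tcim, by 0.91 ± 0.19. AK088220 was at least 1.84-fold lower. Cry1 fell by 0.79 ± 0.15 (adjusted p = 0.0347), the 1 of 18 clock genes past the threshold, whereas Dbp was at 0.08 ± 0.16 and Per1 at -0.06 ± 0.22; adjusted over the list alone 2 clock genes were higher and 4 lower (median -0.18, adjusted p = 0.915, and 0.954 with an estimated correlation).

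Collagen and fibrosis genes had a median of 1.26 over 40 genes in T3R1. Of these 16 were higher, and adjusted over the list alone 33 were higher and 1 lower (adjusted p = 2.1e-28, and 0.194 with an estimated correlation). The members of smallest p were Bgn (biglycan, 0.92 ± 0.14), Col1a2 (1.81 ± 0.29), Col16a1 (1.33 ± 0.23) and Col6a2 (1.09 ± 0.19). Fibroblast markers had a median of 0.32 over 12 genes, with 4 higher, or 6 higher and 1 lower adjusted over the list alone, Mfap5 (1.48 ± 0.29) among them (adjusted p = 2.67e-05, and 0.196 with an estimated correlation). Matrix proteases and their inhibitors had a median of 0.70 over 22 genes, or 0.31 after normexp correction and 0.41 on the authors' values. Here 2 were higher, the membrane collagenase Mmp14 (1.72 ± 0.26) and the procollagen protease Adamts2 (1.29 ± 0.26), and adjusted over the list alone 9 were higher and 2 lower (adjusted p = 3.67e-06, and 0.194 with an estimated correlation). Cell cycle genes had a median of 2.23 over 31 genes, or 3.25 without control replicate 1, 1.255 after normexp correction and 1.47 on the authors' values, with 1 past the threshold, Ube2c, or 28 adjusted over the list alone (adjusted p = 3.14e-21, and 0.385 with an estimated correlation). Kif11 was at 3.29 ± 0.79, Cdc20 at 2.10 ± 0.52, Nusap1 at 2.13 ± 0.53 and Mki67 at 2.66 ± 0.71, with adjusted p from 0.0613 to 0.0705. The hypertrophy and fetal program had a median of 0.80 over 20 genes, with Mybpc2 (1.22 ± 0.25) and the ubiquitin hydrolase Uchl1 (1.05 ± 0.22) higher, or 6 adjusted over the list alone (adjusted p = 3.72e-07, and 0.532 with an estimated correlation). Myh7 (1.01 ± 0.60), Nppb (0.39 ± 0.49), Nppa (0.12 ± 0.16), Fkbp5 (0.06 ± 0.15), Pdk4 (-0.84 ± 0.41), Ucp3 (-0.05 ± 0.09), S100a8 (0.28 ± 0.82), Hba-a1 (0.01 ± 0.31) and Hspa1a (0.20 ± 0.71) stayed short of the threshold.

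Fatty acid oxidation had a median of -0.50 over 30 genes in T3R1, with 0 past the threshold in limma and 15 lower adjusted over the list alone (adjusted p of the list = 6.79e-07, and 0.666 with an estimated correlation). Decr1 (-0.56 ± 0.15), Acot2 (-0.59 ± 0.17), Hadhb (-0.56 ± 0.17) and Ech1 (-0.72 ± 0.22) led it. Oxidative phosphorylation had a median of -0.34 over 44 genes, with Ndufa1 at -0.51 ± 0.16 and Cox7a1 at -0.63 ± 0.21 (adjusted p = 6.79e-07, and 0.799 with an estimated correlation). The citric acid cycle (-0.32 over 19 genes, adjusted p = 0.00114) and ion channels (-0.33 over 19, adjusted p = 0.0129) were called with 0 genes past the threshold, over all genes and adjusted over each list alone, as in oxidative phosphorylation; their adjusted p was 0.799 with an estimated correlation. Endothelial markers had a median of -0.31 over 14 genes, with 0 past the threshold and 6 lower adjusted over the list alone (adjusted p = 0.000143, and 0.447 with an estimated correlation). Against control replicates 2 to 4, 41 oxidative phosphorylation genes, 25 fatty acid oxidation genes, 15 citric acid cycle genes and 12 of 20 sarcomere genes were lower. Then 33 collagen genes and 30 cell cycle genes were higher.

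Macrophage markers had a median of 0.59 over 20 genes in T3R1, with 0 past the threshold, and 10 higher and 3 lower adjusted over the list alone (adjusted p = 2.67e-05, and 0.447 with an estimated correlation). Of these C1qc (0.64 ± 0.16), Cd68 (1.41 ± 0.35) and the mannose receptor Mrc1 (0.97 ± 0.28) were positive and Timd4 (-0.98 ± 0.22) negative. Interferon-induced genes had a median of 0.27 over 34 genes. The ubiquitin-like Isg15 was higher by 0.91 ± 0.17 and Gbp4 was lower, and adjusted over the list alone 12 were higher and 4 lower (adjusted p = 0.000353, and 0.799 with an estimated correlation). Inflammatory cytokines had a median of 0.64 over 33 genes, with Cxcl10 at 2.94 ± 0.65 (adjusted p = 0.054) and Ccl8 at 2.43 ± 0.60; 0 were past the threshold, and adjusted over the list alone 3 were higher and 1 lower (adjusted p = 0.00016, and 0.791 with an estimated correlation). Complement and acute-phase genes had a median of 0.28 over 28, or 0.66 without control replicate 1, with Serpina3n at 2.77 ± 0.69 and Lcn2 at 2.76 ± 0.71 (adjusted p = 0.0658); 0 were past the threshold and 3 adjusted over the list alone (adjusted p = 0.000418, and 0.791 with an estimated correlation). The coagulation list had a median of 0.36 over 26 genes, with thrombomodulin Thbd lower by 0.48 ± 0.10, and adjusted over the list alone 7 were higher and 2 lower (adjusted p = 0.000553, and 0.385 with an estimated correlation). Cholesterol synthesis (0.27 over 20 genes, adjusted p = 0.00157, and 0.791 with an estimated correlation) and erythroid markers (0.47 over 13, adjusted p = 0.0169, and 0.799 with an estimated correlation) had 0 genes past the threshold, over all genes and over each list alone. The erythroid list was not called without control replicate 1 (median 0.27) or T3R1 replicate 2 (0.24).

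Camera called 17 lists in T3R1, 12 up and 5 down. With an estimated correlation 0 were called, and fry called 17 in either direction and 5 in a common direction: collagen and fibrosis (adjusted p = 0.00972), fibroblast markers (0.0116), matrix proteases (0.0157), endothelial markers (0.021) and the cell cycle (0.0489). The count of 157 genes rested on single arrays. It was 6672 without control replicate 1, 3 without control replicate 2, 8 without control replicate 3, 9 without control replicate 4, 12 without T3R1 replicate 1, 62 without T3R1 replicate 2, 18 without T3R1 replicate 3 and 98 without T3R1 replicate 4. Arrays outside this comparison, which enter its estimate of the spread, moved it too: it was 257 without T1R1 replicate 2, 98 without T1R1 replicate 4, 100 without T2R1 replicate 2, 71 without T2R1 replicate 3 and 73 without T2R1 replicate 4. Of 33 genes named by rule and past the threshold, Gbp4 alone stayed past it without each array; 32 fell short without any 1 of control replicates 2 to 4 or T3R1 replicate 1.

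**Figure D3:**
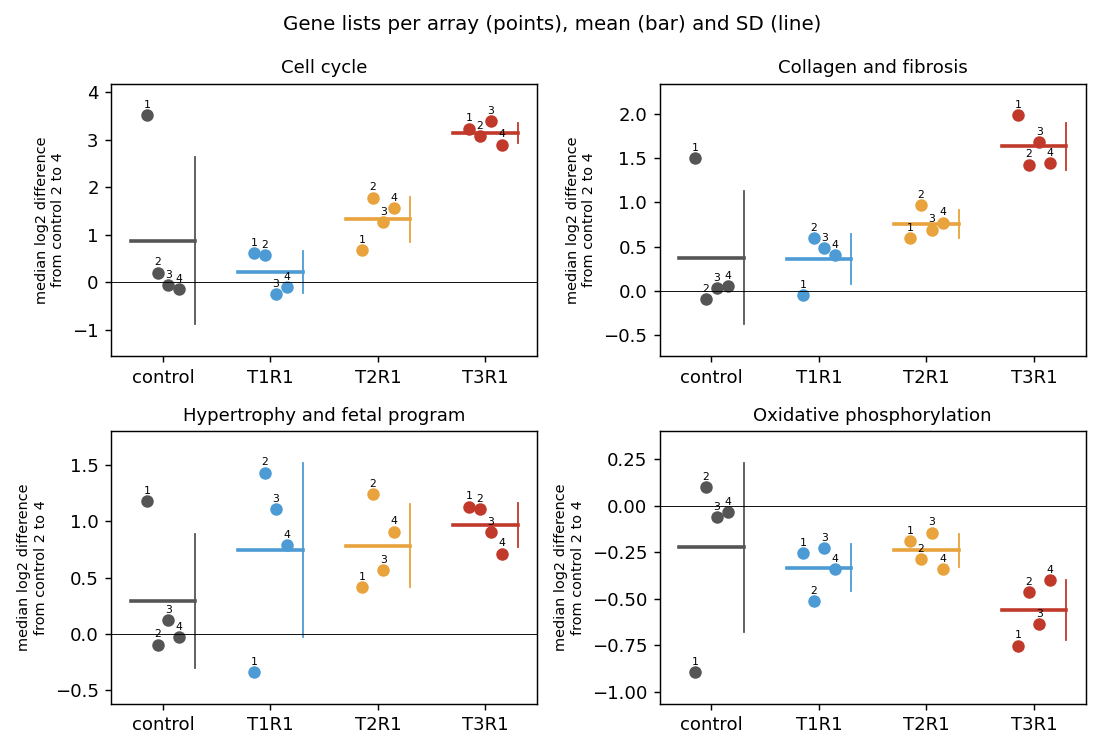
Median log2 difference from the mean of control replicates 2 to 4 (y axis) of the cell cycle, collagen and fibrosis, hypertrophy and fetal program and oxidative phosphorylation lists, for each array by group (x axis), with a bar at the group mean and a line of 1 SD. Control replicate 1 lies at 3.52 for the cell cycle, above the highest T3R1 array, which lies at 3.39.

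T2R1 and T1R1, on the same slide, were compared to ask what a second day of exposure adds. At a preset correlation the ribosomal protein, collagen, cell cycle and platelet lists were called upward and interferon and vessel lists downward, but none was called with an estimated correlation or by fry. No single gene passed: limma called 0 genes, with 1775 at an unadjusted p under 0.05 and a lowest adjusted p of 0.342, and every other normalization, filter and fit tried gave 0 at an adjusted p under 0.05. Camera called 10 of the 43 lists, 4 up and 6 down; 0 were called with an estimated correlation, 0 by fry in a common direction and 0 by fry in either direction. This list test was chosen after the slides were known.

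Platelet markers had a median of 1.00 over 13 genes in T2R1 minus T1R1, with 0 past the threshold in limma and 10 higher adjusted over the list alone (adjusted p = 2.97e-09, and 0.575 with an estimated correlation). The platelet receptor genes Gp1bb (1.18 ± 0.29), Gp1ba (1.42 ± 0.39), Itgb3 (1.17 ± 0.29) and Treml1 (1.43 ± 0.38) led, each at an adjusted p of 0.635 over all genes. In the other 9 lists 0 genes passed, over all genes and adjusted over the list alone. Cell cycle genes had a median of 0.98 over 31 (adjusted p = 1.21e-06, and 0.974 with an estimated correlation), with Tk1 at 1.12 ± 0.43, Cdk1 at 2.26 ± 0.93 and Mki67 at 1.64 ± 0.71. Collagen genes had a median of 0.42 over 40 (adjusted p = 0.000347, and 0.974), with Col1a1 at 1.07 ± 0.42, Col3a1 at 1.26 ± 0.50 and Col12a1 at 1.95 ± 0.72. Ribosomal proteins had a median of 0.17 over 40 (adjusted p = 2.97e-09, and 0.914), with Rps20 at 0.23 ± 0.08, and this median was 0.04 with quantile normalization and 0.01 on the authors' values. Interferon-induced genes had a median of -0.25 over 34 (adjusted p = 1.25e-08, and 0.914), with Gbp4 at -0.47 ± 0.17 and Iigp1 at -0.38 ± 0.15. Endothelial markers (-0.07 over 14; Tek -0.36 ± 0.12; adjusted p = 0.00486, and 0.914) and angiogenesis genes (-0.07 over 26; Aplnr -0.56 ± 0.21; adjusted p = 0.0093, and 0.914) were lower. So were epicardial markers (-0.36 over 10; Upk3b -0.51 ± 0.32; adjusted p = 0.00343, and 0.974), atrial markers (-0.25 over 10; Bmp10 -0.74 ± 0.34; adjusted p = 0.0236, and 0.974) and oxidative stress genes (-0.10 over 18; Gclc -0.26 ± 0.11; adjusted p = 0.01, and 0.259), the second value being that with an estimated correlation. Without T1R1 replicate 1 the collagen (0.27), atrial (-0.13) and epicardial (-0.11) lists were no longer called, and without T1R1 replicate 3 the oxidative stress (-0.05) and angiogenesis (-0.06) lists. The atrial list also lost its call without T1R1 replicate 4 (-0.18), T2R1 replicate 2 (-0.16) or T2R1 replicate 4 (-0.10).

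T3R1 was compared with T1R1 to ask what separates 3 days of exposure from 1, between slides. Nearly the whole cell cycle list and most of the collagen list were higher in T3R1, with osteopontin and genes of cholesterol synthesis. Crhbp, Cd247, Dbp and Tat were lower in T3R1. In all 5183 genes changed, 1729 higher and 3454 lower, and 8269 had an unadjusted p under 0.05. With each array scaled to its median the balance was reversed, 7463 higher and 1283 lower, and on the authors' values 2334 were higher and 2589 lower. Without control replicate 1, which enters the estimate of the spread alone, 7097 genes changed.

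Of 31 cell cycle genes 30 were higher in T3R1 than in T1R1, and 30 adjusted over the list alone (median 2.84, adjusted p = 3.76e-17, and 0.483 with an estimated correlation). Mki67, a proliferation antigen on chromosome 7 at 142881591 to 142881650, was 12.6-fold higher (3.65 ± 0.71, adjusted p = 0.0025), and the spindle gene Aspm (chromosome 1 at 141390377 to 141390436) at least 9.10-fold. The kinetochore gene Ska1 was at least 5.78-fold higher. The mitotic kinase Pbk was higher, with 1 of 4 T1R1 arrays well above background. Cdca3 rose by 4.28 ± 0.82, thymidine kinase Tk1 by 2.55 ± 0.43 and Cdc20 by 2.84 ± 0.52. Of 40 collagen and fibrosis genes 30 were higher, or 32 adjusted over the list alone (median 1.19, adjusted p = 1.89e-18, and 0.483 with an estimated correlation). Cthrc1 (adjusted p = 0.00215) and Crct1 were higher, with 1 of 4 T1R1 arrays well above background for each. Postn was 9.46-fold higher (3.24 ± 0.64) and Col1a1 5.95-fold (2.57 ± 0.42). Col3a1 rose by 2.62 ± 0.50, Col1a2 by 2.22 ± 0.29, Col14a1 by 1.82 ± 0.26 and Mmp14 by 1.78 ± 0.26. Spp1 (osteopontin, chromosome 5 at 104868502 to 104868561) rose by 4.17 ± 1.31 and Sprr1a (chromosome 3 at 92287955 to 92288014) by 4.52 ± 1.37. Fibroblast markers (0.46 over 12 genes, 7 higher, 8 adjusted over the list alone; adjusted p = 9.34e-06, and 0.392 with an estimated correlation) and matrix proteases (0.55 over 22, 6 higher, and 7 higher and 2 lower adjusted over the list alone; adjusted p = 0.000587, and 0.483) were called too. Cholesterol synthesis had a median of 0.65 over 20 genes, or 0.34 after normexp correction, with 8 higher, Cyp51 (0.77 ± 0.16), Fdps (0.66 ± 0.14) and Hmgcs1 (0.41 ± 0.10) among them, and adjusted over the list alone 14 were higher and 1 lower (adjusted p = 1.69e-06, and 0.574 with an estimated correlation).

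Macrophage markers had a median of 0.63 over 20 genes in T3R1 minus T1R1. Of these 10 were higher and 3 lower, or 12 and 3 adjusted over the list alone, with C1qc at 0.75 ± 0.16, Emr1 at 1.15 ± 0.25 and Ly6c1 at -0.52 ± 0.12 (adjusted p = 0.000832, and 0.786 with an estimated correlation). Interferon-induced genes had a median of 0.30 over 34, with 12 higher, Isg15 (1.00 ± 0.17) among them, and Gbp4 lower (-1.15 ± 0.17), or 13 and 1 adjusted over the list alone (adjusted p = 0.000247, and 0.883). Adipocyte markers had a median of 2.04 over 14 genes, with Ucp1 (5.76 ± 1.68) and Cidea (0.72 ± 0.24) higher, or 4 adjusted over the list alone (adjusted p = 0.000247, and 0.883). The difference rested on T1R1 replicates 2 to 4, since T1R1 replicate 1 lay at 0.47, among the T3R1 arrays at -0.66 to 0.69 against control replicates 2 to 4. Ribosomal proteins had a median of 0.13 over 40, with 4 higher, Rps28 (0.40 ± 0.09) first, or 1 adjusted over the list alone (adjusted p = 2.68e-05, and 0.883). Platelet markers had a median of 0.42 over 13, or 0.13 after normexp correction, with Pf4 (0.48 ± 0.15) and Itgb3 (0.86 ± 0.29) higher, or 0 adjusted over the list alone (adjusted p = 0.0172, and 0.883). Fatty acid oxidation had a median of -0.35 over 30 genes, which turned to 0.05 with arrays scaled to their median, a shift shared by all genes, whose median went from -0.07 to 0.33. Its genes Acot2 (-0.74 ± 0.17), Ech1 (-0.74 ± 0.22), Lpl (-0.51 ± 0.17) and Acadm (-0.50 ± 0.17) were lower, or 1 adjusted over the list alone (adjusted p = 0.0142, and 0.915). The second adjusted p of each pair is that with an estimated correlation. Of the 11 lists called, 10 up and 1 down, 0 were called with an estimated correlation, 8 by fry in a common direction and 23 in either direction; without T1R1 replicate 3 the fatty acid oxidation (-0.30) and platelet (0.20) lists, and without T3R1 replicate 2 the platelet list (0.21), were no longer called.

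Crhbp fell by 2.36 ± 0.31 from T1R1 to T3R1 (adjusted p = 0.000247), the transporter gene Slc16a5 by 2.35 ± 0.58, F7 by 0.73 ± 0.13, Thbd by 0.67 ± 0.10 and Cd247 by 0.64 ± 0.16. The T cell coreceptor gene Cd8a was at least 2.07-fold lower. Thymus markers were too few for a test. Their median was -1.23, or -0.75 after normexp correction and -0.58 on the authors' values, and T1R1 replicate 1 stood apart in them. The casein gene Csn1s2b was at least 3.98-fold lower and 1700063H04Rik at least 6.16-fold. Dbp fell by 0.77 ± 0.16 (adjusted p = 0.00427), Cry2 by 0.47 ± 0.13 and Tat by 1.33 ± 0.24 (adjusted p = 0.00152), whereas Arntl rose by 0.84 ± 0.27 (adjusted p = 0.0357). Liver markers had a median of -0.35 and lay at 4.10 on T1R1 replicate 4 against control replicates 2 to 4. The other T1R1 arrays lay from -0.31 to 1.10 and the T3R1 arrays from -0.48 to 2.84. Both F7 and Tat stayed past the threshold without each array in turn, T1R1 replicate 4 included. These values argue against liver RNA as the whole source of the lower F7 and Tat in T3R1. The clock list (median -0.28, adjusted p = 0.473, and 0.915 with an estimated correlation) and the glucocorticoid list (-0.11, adjusted p = 0.777, and 0.97) were not called. Past the threshold were 1 clock gene higher and 3 lower, or 1 and 4 adjusted over the list alone, and 3 glucocorticoid genes lower, or 1. Fkbp5 was at 0.36 ± 0.15, Per1 at -0.53 ± 0.22, Myh7 at 0.08 ± 0.60, Nppa at 0.20 ± 0.16, Nppb at -0.49 ± 0.49, Pdk4 at -0.47 ± 0.41, Ucp3 at -0.21 ± 0.09, S100a8 at -0.82 ± 0.82, Hspa1a at -1.05 ± 0.71, Hba-a1 at 0.21 ± 0.31 and Lcn2 at 0.77 ± 0.71, with adjusted p from 0.0922 to 0.936. Of 80 genes named by rule and past the threshold, 57 stayed past it without each array; 18 fell short without T3R1 replicate 1, 17 without each of T3R1 replicate 2, T1R1 replicate 1 and T1R1 replicate 3, 16 without T1R1 replicate 4 and 15 without T3R1 replicate 3.

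T3R1 was also compared with T2R1, between slides. Postn and Mki67 were higher and the clock genes Dbp and Per1 lower in T3R1; lists were not tested. In all 6104 genes changed, 1489 higher and 4615 lower, and 8303 without control replicate 1. With each array scaled to its median 5493 were higher and 2190 lower, the opposite balance. Postn rose by 2.03 ± 0.64 (adjusted p = 0.0304) and Mki67 by 2.01 ± 0.71 (adjusted p = 0.0486). Dbp fell by 1.08 ± 0.16 (adjusted p = 0.000354), Per1 by 0.83 ± 0.22 (adjusted p = 0.0122), Gm129 by 1.61 ± 0.39 (adjusted p = 0.00784), Crhbp by 2.08 ± 0.31 (adjusted p = 0.000355), Retnlg by 2.41 ± 0.81 (adjusted p = 0.0412) and Gbp4 by 0.68 ± 0.17 (adjusted p = 0.00949). Arntl rose by 1.31 ± 0.27 (adjusted p = 0.00258). Of these Gm129, Crhbp, Retnlg, Gbp4 and Arntl were chosen here after their values were seen.

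The mean of the 3 exposure groups was compared with control to ask what the exposures had in common on average. Higher on average were Lcn2 (2.44 ± 0.58, adjusted p = 0.0252), Gm129 (2.01 ± 0.32, adjusted p = 0.0066), Crhbp (0.97 ± 0.26, adjusted p = 0.0388) and Dbp (0.70 ± 0.13, adjusted p = 0.0121). The averages of Crhbp and Dbp rested on T1R1 and T2R1, since in T3R1 against control Crhbp was at -0.50 and Dbp at 0.08. Lower on average were Arntl (-1.05 ± 0.22, adjusted p = 0.0157), Gbp4 (-0.80 ± 0.14, adjusted p = 0.00927) and Cry1 (-0.65 ± 0.12, adjusted p = 0.0121). The average of Arntl also rested mostly on T1R1 and T2R1, since Arntl was higher in T3R1 than in either. Of the genes averaged here all but Lcn2 and Dbp were chosen after their values were seen. By limma 1553 genes changed, 1149 higher and 404 lower. Most were lower instead with other background correction or scaling: 297 against 171 higher after normexp correction, 431 against 382 with quantile normalization, 815 against 522 on the authors' values and 6957 against 349 with each array scaled to its median. With other filters most stayed higher: 659 against 109 lower with no filter on dim probes, and 901 against 465 with probes well above background on all 16 arrays. The count was 5870.0 without control replicate 1, 678 without control replicate 3, 347 without control replicate 4 and 983 without T2R1 replicate 4. By the moderated F test 6085 genes differed among the 4 groups, or 11057 without control replicate 1, and 9443 at an unadjusted p under 0.05.

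The 3 exposure groups share the same 4 controls, which alone makes their fold changes alike. Across 22546 genes, which are not independent replicates, the fold changes of T1R1 and T2R1 correlated at r = 0.83. Here 1000 simulated pairs of unchanged groups against these controls gave a median of 0.51, and 0.79 near their upper end. With the controls split so that the groups shared none, r was 0.50 on average, from 0.47 to 0.54. Between T1R1 and T3R1 r was 0.10, and from -0.34 to 0.24 with split controls; between T2R1 and T3R1 it was 0.20, and from -0.24 to 0.34. Without control replicate 1 the 3 values were 0.85, 0.40 and 0.44, and without T1R1 replicate 2 the value for T1R1 and T3R1 was -0.0032. T1R1 and T2R1, which share a slide, had 1642 genes higher in both, 219 lower in both and 0 in opposite directions in limma.

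**Figure D4:**
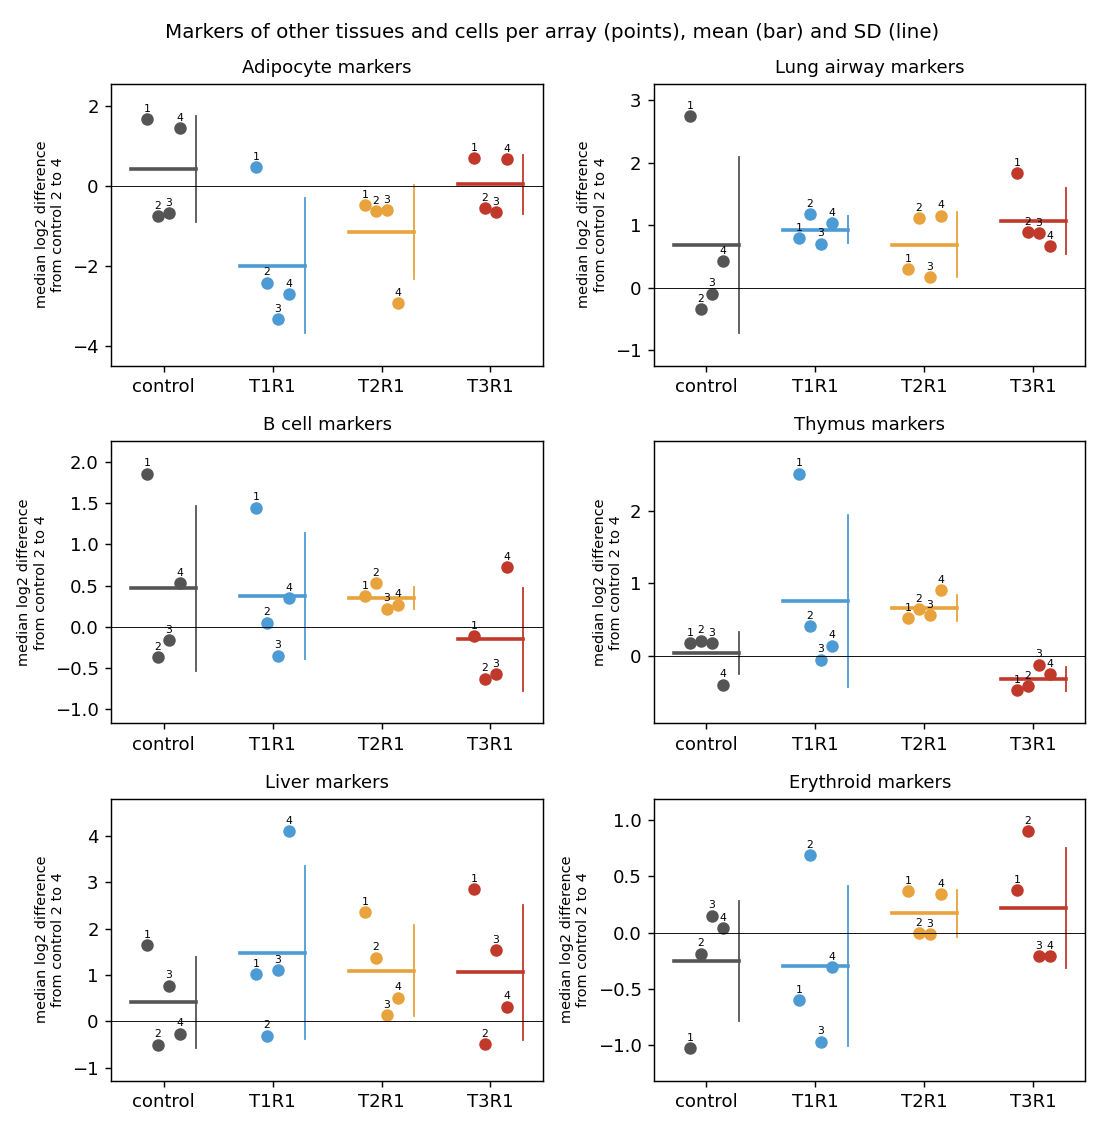
Median log2 difference from the mean of control replicates 2 to 4 (y axis) of adipocyte, lung airway, B cell, thymus, liver and erythroid marker lists, for each array by group (x axis), with a bar at the group mean and a line of 1 SD. Thymus markers lie at 2.51 on T1R1 replicate 1 and lung airway markers at 2.74 on control replicate 1.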

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

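The tests of a wrong label, of an exchange of arrays, of the share of cardiomyocyte RNA and of the scaling were chosen only after the results were seen. The random groupings and the tests of brightness, place and slide were chosen before. The tests of brightness and place set control replicate 1 apart, though, and leaving that array out was a choice made after the files had been seen.

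Control replicate 1 resembled the T3R1 arrays in its main expression pattern. On a scale with 0 at control replicates 2 to 4 and 1 at the T3R1 mean it lay at 1.08, where the T3R1 arrays lay from 0.684 to 1.12 and control replicates 2 to 4 from 0.0702 to 0.138. A wrong label of this array alone could give that place and stays open. In some marker lists the array lay outside the T3R1 arrays, against control replicates 2 to 4. B cell markers lay at 1.86 against -0.63 to 0.72 in T3R1, and erythroid markers at -1.03 against -0.21 to 0.90. An exchange with a T3R1 array was argued against by the lowest T3R1 array, at 0.684, which lay far from the controls. The cell cycle list of this array, at 3.48, exceeded 100% of 10000 lists matched for signal, whose median was -0.174. This argued only against a shift shared by genes of equal signal. Members of the matched lists were drawn independently, and the cell cycle list was the furthest shifted on this array. Other effects of brightness therefore stay open.

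Against control replicates 2 to 4, T3R1 had higher cell cycle and collagen genes and lower oxidative phosphorylation genes. Their medians of 3.17, 1.57 and -0.57 were shifted further than 100% of matched lists, which argued against brightness as the whole cause. Matched lists tested only a shift shared by genes of equal signal. With quantile normalization the medians without control replicate 1 were 3.15, 1.60 and -0.32. On the authors' values they were 2.07, 1.53 and -0.26, so the sizes depended on the processing. A loss of cardiomyocyte RNA alone would raise all other cells alike, but macrophage markers rose by 0.77 and endothelial markers fell by 0.41. The gap was 1.19 with a standard error of 0.114, so such a loss alone could not be the whole cause. A rise of only some other cells would also lower the cardiomyocyte share. The test could not decide on that, and a changed mix of cells stays open. Place on the slide would give the same pattern in T2R1 minus T1R1, and the slope there was 0.293 with a standard error of 0.106 over 113 genes, from 0.242 to 0.355 with an array left out. A slope of 1 was what place alone would give, so place could not be the whole cause.

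More genes were higher than lower in T1R1 and T2R1 against control, which lay on the other slide. Of the 1755 genes higher in T1R1 than in control, 99.6% were also higher in T2R1 than in T3R1, against 60.9% of all genes, so slide and exposure cannot be told apart. Scaling or background correction may have made the imbalance as well. In T1R1 the share that was higher was 51.7% with quantile normalization, 50.8% after normexp correction, 46.0% on the authors' values and 5.81% with arrays scaled to their median. In T2R1 these shares were 60.8%, 67.9%, 56.8% and 15.2%, so the imbalance of T1R1 depended on the processing, and the cause stays open.

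Groups were exchanged at random, and the number of groupings with a result as large, the real one included, is given with the highest other value. For genes changed, the real grouping gave the most in T2R1 against control (1 of 35, highest other 2), T3R1 against T1R1 (1 of 35, highest other 5) and T3R1 against T2R1 (1 of 35, highest other 2). These pairs of groups lay on different slides, so the real grouping was also that of the slides, and slide could give this result too. The real grouping also gave the most for the mean of the exposures against control (1 of 100, highest other 343) and the 4 groups together (1 of 100, highest other 5592). Chance could not be excluded in T1R1 against control (2 of 35, highest other 2876, where control replicate 1 was exchanged with T1R1 replicate 1) or in T3R1 against control (3 of 35, highest other 7003, where control replicate 1 was exchanged with T3R1 replicate 4, which points to a structure of the samples). In T2R1 against T1R1 the real count was 0, so the groupings tested nothing (35 of 35, highest other 0). For the number of lists called chance could be excluded nowhere: T1R1 against control 35 of 35 (highest other 29), T2R1 against control 32 of 35 (31), T3R1 against control 22 of 35 (29), T2R1 against T1R1 30 of 35 (21) and T3R1 against T1R1 31 of 35 (20).

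A test for a single array far from the other 3 of its group marked 30 of 260 cases, where chance marks about 1 in 20 groups and 13 were due. Control replicate 1 differed from the mean of the other controls by 3.52 in the cell cycle list, 1.56 in inflammatory cytokines, 1.497 in collagen and fibrosis, 1.18 in the hypertrophy and fetal program and 0.44 in fibroblast markers. It differed by -0.97 in cardiomyocyte markers, -0.89 in oxidative phosphorylation, -0.89 in the sarcomere, -0.81 in fatty acid oxidation, -0.73 in the citric acid cycle, -0.72 in ion channels, -0.51 in skeletal muscle markers and -0.36 in glycolysis. Among genes it differed by 3.81 in Mki67, 3.64 in Postn, 3.24 in Lcn2, 2.82 in Col3a1, 2.38 in Col1a1 and -1.13 in Hba-a1. Its 75th percentile was 282.3 scanner units higher, and it had 23 more spots marked as outliers.

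Elsewhere the same test marked control replicate 4 in the glucocorticoid list (0.46) and in thymus markers (-0.58), T1R1 replicate 1 in Nppb (-2.40), T1R1 replicate 2 in calcium and adrenergic genes (-0.23) and in skeletal muscle markers (-0.20), T2R1 replicate 3 in complement genes (-0.34), T2R1 replicate 4 in the glucocorticoid list (-0.46) and in adipocyte markers (-2.35), and T3R1 replicate 4 in T and NK cell markers (0.37). Exposures differed from each other in 5183 genes between T3R1 and T1R1, in 6104 between T3R1 and T2R1, in 10 lists between T2R1 and T1R1 and in 11 lists between T3R1 and T1R1, of which 0 were called with an estimated correlation in either comparison. The negative control spots of T2R1 replicate 4 had a mean signal of 595.8, against 33.9 to 43.4 on the other arrays. The SD of their background-subtracted signal was 2.33, where the other arrays had 2.11 to 4.27. The cause was not tested.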

How the results depend on the processing

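The fits without both control replicate 1 and T1R1 replicate 1, the fold changes of all genes without control replicate 1 and the list tests of T2R1 against T1R1 were chosen only after results were seen; all other settings were chosen before. Where a value moved, the cause was not tested. Counts are of genes past the threshold unless lists are named.

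With normexp background correction the counts were 1100.0 in T1R1 against control, 2595 in T2R1, 296 in T3R1 and 468 for the mean of the exposures, and 10 lists were called in T1R1. With quantile normalization they were 1409 in T1R1 and 813 for the mean. With each array scaled to its median they were 10687 in T1R1, 9102 in T2R1, 21 in T3R1, 8746 in T3R1 against T1R1, 7306 for the mean and 12686 for the 4 groups, and 8 lists were called in T1R1; Tef in T3R1 against T1R1 turned to 0.0153. On the authors' values 368 genes changed in T3R1.

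With no filter on dim probes the counts were 17 in T3R1 and 768 for the mean, with 19 lists called in T1R1 and 20 in T3R1 against T1R1. Gnal, which another probe then represented, turned to 0.22 in T1R1 and 0.0223 in T2R1. With probes well above background on all 16 arrays 535 genes changed in T3R1. With only the 2 groups compared in the fit 972 changed in T1R1 and 2 in T3R1. With an intensity trend and robust prior 480.0 changed in T3R1.

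With array weights, where control replicate 1 had a weight of 0.140, the counts were 4329 in T1R1, 8780.0 in T2R1, 7840.0 in T3R1, 9289 in T3R1 against T2R1, 8503 for the mean and 13163 for the 4 groups, with 19 lists called in T1R1 and 15 in T2R1. With the replicate block 42 genes changed in T3R1, 2256 in T1R1 and 4091 in T2R1. Slide and scan as blocks could not be fitted.

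At an adjusted p under 0.05 with at least a 1.5-fold change 683 genes changed for the mean. At an adjusted p under 0.10 the counts were 3635 in T1R1, 1531 in T3R1 and 3161 for the mean, with 9 lists in T1R1 and 20 in T3R1 against T1R1. At an unadjusted p under 0.05 they were 5862 in T1R1, 6988 in T2R1, 5085 in T3R1, 1775 in T2R1 against T1R1, 8269 in T3R1 against T1R1, 5944 for the mean and 9443 for the 4 groups, with 13 lists in T1R1 and 20 in T3R1 against T1R1.

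Without both control replicate 1 and T1R1 replicate 1 the counts were 4975 in T1R1, 7035 in T3R1, 6518 for the mean and 11582 for the 4 groups, with 20 lists in T1R1 and 15 in T2R1. Col1a1 in T1R1 turned to 0.51, Col3a1 to 0.84 and Postn to 1.05, and Myh7 in T3R1 against T1R1 turned to -0.63.

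With camera and an estimated correlation 0 lists were called in each of the 5 comparisons. Without control replicate 1 this was 1 in T3R1 against T1R1 and 0 in the others. With fry in a common direction 0 were called in T1R1, 1 in T2R1, 5 in T3R1 and 0 in T2R1 against T1R1. With fry in either direction 6 were called in T1R1, 8 in T2R1 and 17 in T3R1 against control, 0 in T2R1 against T1R1 and 23 in T3R1 against T1R1.

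Scaling arrays to their median shifted the medians of most lists with those of all genes. In T3R1 against control the interferon list went from 0.27 to 0.30, while the median of all genes went from -0.08 to -0.11. Other settings moved medians of called lists by 1.5-fold or more. With normexp correction the cell cycle list was at 1.255 in T3R1 against control, 1.79 in T3R1 against T1R1 and 0.55 in T2R1 against T1R1, and matrix proteases were at 0.31 and 0.25 in the first 2 of these. Cholesterol synthesis was then at 0.14 and 0.34 in the same comparisons. Against control in T3R1 cytokines were then at 0.28, coagulation at 0.15 and complement at 0.18, and in T3R1 against T1R1 platelet markers at 0.13 and ribosomal proteins at 0.21. On the authors' values the medians in T3R1 against control were 1.47 for the cell cycle, 0.41 for matrix proteases, 0.33 for cytokines and -0.19 for both oxidative phosphorylation and the citric acid cycle, and with quantile normalization the last 2 were at -0.21 and -0.20. In T2R1 against control the neutrophil list was at 0.63 with normexp correction, and on the authors' values at 0.67 with angiogenesis at -0.07. In T2R1 against T1R1 endothelial markers were at -0.13 on the authors' values and -0.12 with quantile normalization, and angiogenesis at -0.11 on the authors' values. Leaving out control replicate 1, the neutrophil, angiogenesis and endothelial lists in T2R1 were at 1.71, -0.25 and -0.25, and oxidative phosphorylation, the citric acid cycle, ion channels and cholesterol synthesis in T3R1 at -0.57, -0.51, -0.53 and 0.42.

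With the controls split between the exposures, the correlation of fold changes was 0.50 for T1R1 and T2R1, -0.048 for T1R1 and T3R1, a reversed sign, and 0.0498 for T2R1 and T3R1. Over genes differing among the 4 groups it was -0.23 for T1R1 and T3R1 and -0.0303 for T2R1 and T3R1, both reversed, as was the value of -0.0032 for T1R1 and T3R1 without T1R1 replicate 2.

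Leaving out each array in turn gave 1339 to 4046 genes in T1R1 against control, 3 to 6672 in T3R1 against control, 347 to 5870.0 for the mean and 4360.0 to 11057 for the 4 groups. Lists called ran from 4 to 23 in T1R1 and from 6 to 16 in T2R1. The correlation ran from -0.0032 to 0.40 for T1R1 and T3R1 and from 0.13 to 0.44 for T2R1 and T3R1. Counts that kept within 1.5-fold were 2802 to 5514 in T2R1 against control, 3481 to 7097 in T3R1 against T1R1 and 4193 to 8303 in T3R1 against T2R1.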

Other observations

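All comparisons below were chosen only after the marker lists had been seen, and none was tested.

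Markers of neighbouring tissues varied between hearts of the same group. Against the mean of control replicates 2 to 4, thymus markers lay at 2.51 on T1R1 replicate 1 and between -0.05 and 0.42 on the other T1R1 arrays. Lung airway markers lay at 2.74 on control replicate 1, with B cell markers at 1.86, liver markers at 1.64 and erythroid markers at -1.03. Liver markers reached 4.10 on T1R1 replicate 4, 2.84 on T3R1 replicate 1 and 2.35 on T2R1 replicate 1. Adipocyte markers lay at 0.47 on T1R1 replicate 1 against -2.42, -3.34 and -2.70 on T1R1 replicates 2 to 4, at -2.93 on T2R1 replicate 4 and at 1.45 on control replicate 4.

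T1R1 replicate 1 lay nearer to control replicates 2 to 4 than the other T1R1 arrays did. On the scale from those controls to T3R1 it lay at 0.141, against 0.267 to 0.538 for T1R1 replicates 2 to 4 and 0.237 to 0.537 for T2R1. Its hypertrophy and fetal program lay at -0.34, against 1.43, 1.11 and 0.79 on the other T1R1 arrays, and its collagen list at -0.05, against 0.59, 0.49 and 0.40. Its label was not settled: its correlations lay from 0.984 to 0.989 with the T2R1 arrays, which shared its slide, and from 0.986 to 0.988 with control replicates 2 to 4. With the other T1R1 arrays they lay from 0.981 to 0.984, about as those arrays did with each other. With it and control replicate 1 exchanged, 2876 genes changed in T1R1 against control, where 2231 did in the real grouping, though this exchange moves control replicate 1 as well.

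The cell cycle list lay, against control replicates 2 to 4, from -0.24 to 0.61 on T1R1 arrays, from 0.69 to 1.78 on T2R1 arrays and up to 3.39 on T3R1 arrays, but at 3.52 on control replicate 1. Collagen lists lay from 0.60 to 0.97 on T2R1 arrays and from 1.42 to 1.98 on T3R1 arrays. Platelet markers lay at 1.20 on T2R1 replicate 1 and at -1.09 on T1R1 replicate 3.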
